A study of Pimephales promelas with 15 samples.

How the data were processed

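Livers of 15 male fathead minnows were profiled on one-colour (Cy3) Agilent arrays, 1 fish per array, after 48 h in stormwater, streamwater, wastewater or control water. Fish were kept 4 to a 40 L aquarium with 25 L of water, in 4 aquaria per water, per the labels' design text. Per the labels' protocols, total RNA with an integrity number between 8 and 9.9 was used, and 1000 ng was labelled. Groups and replicate numbers were taken from the sample titles.

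The scanner files hold spot intensities that Agilent Feature Extraction wrote, version 10.1.1.1 per the file headers and version 9.5 per the submitters' processing notes. Their processed signal is an intensity after background subtraction within the array and before any normalization between arrays, per the file headers. The series' value table, deposited by the authors, holds 1 column per array on a log2 scale. Set against log2 of the processed signal, its columns correlated at 0.993 to 1.00 across probes. Their medians lay between 8.36 and 8.59 and their means between 8.76 and 8.79. Apart from 1 probe missing from the table, each column had as many blanks as the scanner file marks outlier spots. Whether these are the same spots was not checked. The method that brought the columns to a common level is not given in the sources used here. That table served only as an alternative.

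From the scanner files, log2 of the processed signal was taken, the 75th percentile of the 15208 non-control probes was subtracted per array, and spots marked as non-uniform or population outliers were set to missing. Each probe has 1 spot. Probes well above background on at least 3 of the 15 arrays (11640) were tested. A probe not well above background on any array of a group has only a bound there. Its ratio is given as "at least" the bright group's mean over the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

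Each comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit with a mean per group over all 15 arrays, contrasts, eBayes, two-sided), which leaves 11 residual degrees of freedom, with Benjamini-Hochberg adjustment within a comparison and a threshold of 0.05. Log2 fold changes are given with limma's standard error. The median 95% confidence interval of a log2 fold change against control reached 1.07 to either side. Single array measures were compared by exact permutation tests, and distances between arrays by a pseudo-F statistic, with permutations of the labels, or all of them where these could be listed. Figures were drawn with matplotlib 3.10.9.

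Before the data were examined, the tests, the alternatives, a rule for named genes and 28 gene lists (pathways that water pollutants act on, liver functions and markers of other cell types) were fixed. For each comparison the rule took the named genes with the largest passing rises and falls whose arrays lay on one side of all arrays of the other group, or those of smallest p where few passed, and members of each list. By the rule, a probe without a gene name was counted and not named. Probe sequences carry contig numbers (11862), sequence numbers (3309) or other names (37), and 0 of them matched the reference gene table of assembly fPimPro1.hap1.1. No list could therefore be tested, neither the rule nor the lists yielded a gene, and the probes named in the text were chosen after their values were seen. They are probes of low p against control that were well above background on every array compared, the probe of lowest p in each comparison, those that passed in a setting with few calls, and 2 probes with a wide range between single livers.

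The fitting was tested on simulated data made with the 11640 probes' own means and spread, with 200 changed probes per run and 10 runs per comparison. For stormwater against control it found 4.78% of 2-fold, 43.6% of 4-fold and 68.6% of 8-fold changes. For streamwater these shares were 5.52%, 47.2% and 69.5%, and for wastewater 6.87%, 43.3% and 67.6%, with 4.8, 4.3 and 4.2 false calls per run. Each probe was drawn independently from a normal distribution. The shares and false calls therefore hold for arrays without differences that many probes share, which the real arrays have.

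Alternatives were quantile normalization, a normexp background (offset 50), no filter on dim probes, only probes well above background on all arrays, slide as a block, the replicate number as a block, trend and robust variance estimates, array weights, only the 2 groups compared, the authors' values, and leaving out each array in turn. The normexp fit used the median signal of all spots, controls included, since the files hold no mean spot signal. Leaving out both distant arrays, alone or with slide as a block, and fits within each slide were added after the data were seen. A fit within a slide has 1 mean per group and slide and pools the spread over all arrays, so that a group with 1 array on a slide is assumed to vary like the others. Slides were read from the array barcodes, 7 arrays on slide 1 and 8 on slide 2. The labels do not say that equal replicate numbers share an aquarium or day.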

Results

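Liver gene expression was measured in male fathead minnows (Pimephales promelas, a small freshwater fish used in aquatic toxicology) after 48 h in 1 of 4 waters. Stormwater came from a lake, streamwater from below a wastewater treatment plant, and wastewater was plant effluent that is used to irrigate landscaping. The control was carbon-filtered, dechlorinated tap water. Each one-colour array held the liver RNA of 1 fish, with 4 fish for each effluent and 3 for the control, so that the number of arrays limits the precision of every comparison. Per the labels' design text each water had 4 aquaria with 4 fish each. The labels do not tie the fish on the arrays to aquaria, so fish that shared an aquarium cannot be recognised and p-values refer to the spread between fish.

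The array carries 15208 non-control probes, of which 11640 were well above background on at least 3 arrays and were tested. The files do not pair probes with gene names, so probes are given by their identifiers, and no gene group could be followed. Between 58.5% and 77.1% of the probes were well above background per array, and the 75th percentile of the signal ran from 1393 to 3981 intensity units. All levels below are log2 signals relative to the 75th percentile of the same array.

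Stormwater replicate 2 and streamwater replicate 4 differed from the other livers. Across probes, which are not independent replicates, they correlated at r = 0.946 with each other and at 0.722 to 0.843 with the other 13 arrays, which correlated at 0.876 to 0.963 among themselves. Of the 100 brightest probes, 28 lay over 16-fold below their median on both arrays, against at most 1 for any other pair of arrays. Over all probes tested, 384 lay over 4-fold below every other array on both, and 21 lay over 4-fold above. Relative to their median, 714 probes lay over 4-fold below on both arrays, and 308 lay over 4-fold above. The first principal component (40.2% of the variance) separated these 2 arrays from the rest, and they came from different slides. Water accounted for 20.8% of the squared distance between arrays (pseudo-F 0.965, permutation p = 0.437, 100000 resamples), and for 25.6% without these 2 arrays (pseudo-F 1.03, permutation p = 0.389). Random labels also account for a share, which grows with the number of groups, and a pseudo-F near 1 is no more than that.

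**Figure D1:**
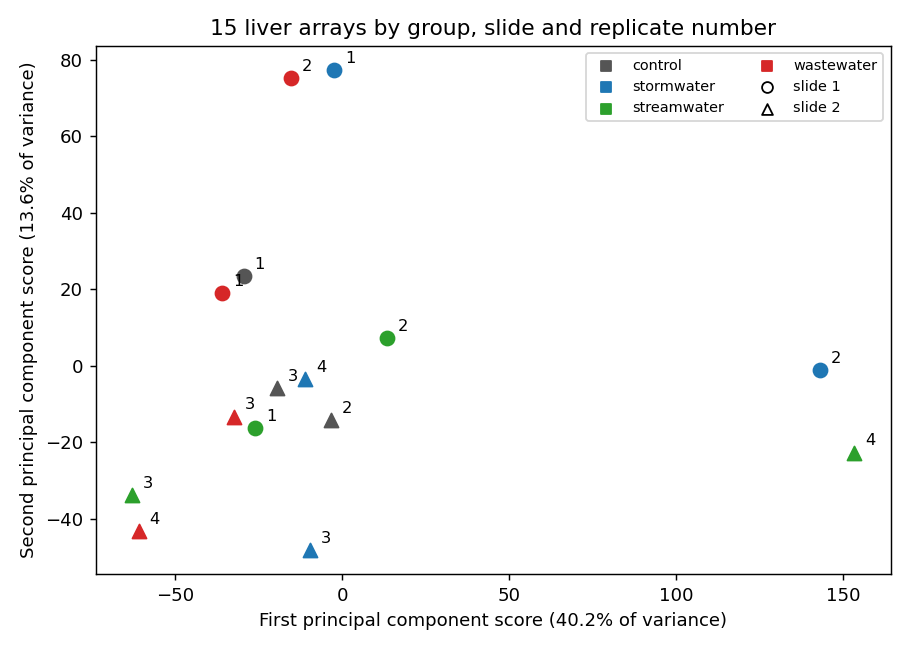
Scores of the 15 liver arrays on the first and second principal components (40.2% and 13.6% of the variance), coloured by water, with the replicate number beside each point and circles and triangles for the 2 slides. Stormwater replicate 2 and streamwater replicate 4 lie at 143.2 and 153.4 on the first component, and the other 13 arrays lie at 13.2 or below.

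Stormwater was set against the control to ask which liver transcripts differed after exposure to lake water. No probe passed limma's test at an adjusted p of 0.05, and the lowest adjusted p was 0.338. The probe of lowest p, UF_Ppr_AF_100386, was at -0.49 ± 0.69 (SD, n = 4) after stormwater and between 2.07 and 2.31 in the 3 controls (SD 0.12), a log2 fold change of -2.69 (SE 0.45), with all 4 exposed livers below all 3 controls. UF_Ppr_AF_110993 was also lower in 4 of 4 exposed livers than in any control, at -1.59 ± 0.33 against 0.02 ± 0.24, a log2 fold change of -1.62 (SE 0.33, limma adjusted p = 0.498). UF_Ppr_AF_118252 was at 0.60 ± 0.97 against -2.14 ± 0.19, a log2 fold change of 2.74 (SE 0.54, limma adjusted p = 0.498), and was higher in 4 of 4 exposed livers than in any control. UF_Ppr_AF_107921 was well above background on all 4 stormwater arrays and on no control array, which puts it at least 3.47-fold higher (limma adjusted p = 0.338). These probes, like the others named here, were chosen after their values were seen.

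At an unadjusted p under 0.05, 774 probes differed between stormwater and control, where 582 would by chance alone. Of these, 223 were higher and 551 lower. The median log2 fold change of all probes was itself -0.21 and moved to -0.02 with quantile normalization, which gave 372 higher and 327 lower, while the authors' values gave 376 higher and 282 lower, so the direction of the excess depended on the scaling. Stormwater and control levels did not overlap in 11.01% of probes (441 above, 834 below), where chance gives 5.71% on average. Probes share differences between arrays, so a single split can lie far from that average. The shares of other splits were not computed. With slide as a block 1443 probes had an unadjusted p under 0.05 and 1 passed limma's test, UF_Ppr_AF_112716 (log2 fold change -1.96, adjusted p = 0.0381, range over all settings 0.0381 to 0.981), which was well above background on 1 of 4 stormwater arrays. Other splits of these arrays within slides gave up to 4 passing probes with the same block. The unadjusted count was 577 within slide 1, which holds 1 control array whose spread is taken from the other groups, 390 within slide 2, 480 without control replicate 1 and 456 without control replicate 2.

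Streamwater was set against the control to ask the same of water below the treatment plant. No probe passed limma's test, and the lowest adjusted p was 0.992. UF_Ppr_AF_100386 was again lower, at 0.41 ± 0.69 (SD, n = 4), a log2 fold change of -1.79 (SE 0.45, limma adjusted p = 0.992). UF_Ppr_AF_105335 was at 1.18 ± 0.36 in streamwater livers and at -0.13 ± 0.20 in controls, a log2 fold change of 1.31 (SE 0.30, limma adjusted p = 0.992), and its log2 fold change after stormwater was 1.18 (SE 0.30). The lowest unadjusted p belonged to UF_Ppr_AF_100352, at -4.76 ± 1.05 in streamwater livers, of which 1 of 4 was well above background, and at 0.66 ± 2.72 in controls, where all 3 were. Its log2 fold change of -5.42 (SE 1.05, limma adjusted p = 0.992) moved to -6.97 without control replicate 1, where it passed (adjusted p = 0.0166), and it also passed within slide 2 (adjusted p = 0.0161), where neither streamwater array was well above background and the ratio is only a bound, with adjusted p from 0.0161 to 1.00 over all settings. The probe was at 2.69 and 1.72 in control replicates 2 and 3 on slide 2 and at -2.43 in control replicate 1 on slide 1. It was also low after stormwater (-3.96 ± 0.93) and wastewater (-3.14 ± 1.18), with log2 fold changes of -4.63 and -3.80 (SE 1.05 for both). No exposed liver of any water lay above -1.87, so control replicates 2 and 3 stood apart from all other arrays.

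At an unadjusted p under 0.05, 469 probes differed between streamwater and control, fewer than the 582 given by chance, with 132 higher and 337 lower. The authors' values gave 207 higher and 220 lower, quantile normalization 223 and 280, and the normexp background 323 and 229, with median log2 fold changes of 0.01, 0.01 and 0.22 in place of -0.10. Streamwater and control levels did not overlap in 5.21% of probes, close to the 5.71% that chance gives on average. The unadjusted count was 726 with slide as a block, with 0 probes passing, 239 within slide 1 (against 1 control array, with the spread of the other groups) and 535 within slide 2. It was 772 without streamwater replicate 3 and 229 without control replicate 2.

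Wastewater was set against the control to ask which transcripts differed after exposure to treated effluent. The clearest difference lay in a single probe. UF_Ppr_AF_119087 was bright in all 4 wastewater livers, at 6.90 ± 0.74 (SD, n = 4), and was not well above background in any of the 3 controls (-6.23 ± 0.38), a difference of at least 2683-fold. It also reached 6.75 in stormwater replicate 4 and 5.10 in streamwater replicate 2, and lay between -5.39 and -1.67 in the other 6 exposed livers. UF_Ppr_AF_118252, which was higher after stormwater, was at 0.70 ± 0.20 after wastewater, a log2 fold change of 2.84 (SE 0.54), and was above all controls in 4 of 4 livers. Neither passed limma's test over all 15 arrays (adjusted p = 0.795 for both).

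The spread of UF_Ppr_AF_119087 within stormwater (SD 5.01) and streamwater (SD 4.54) enters the error of limma's test over all 15 arrays. When only wastewater and control arrays were fitted, 4 probes passed. These were UF_Ppr_AF_119087 (adjusted p = 2.34e-05, range over all settings 2.34e-05 to 1.00), UF_Ppr_AF_118252 (adjusted p = 0.0212, range 0.0212 to 1.00), UF_Ppr_AF_118982 (log2 fold change 4.49, adjusted p = 0.0212, range 0.0212 to 1.00) and UF_Ppr_AF_110291, which was well above background on no wastewater array and so at least 1.69-fold lower (adjusted p = 0.0396, range 0.0396 to 1.00). UF_Ppr_AF_118982 stood at 3.27 ± 0.60 in wastewater livers and at -1.21 ± 0.56 in controls. It also varied widely in the other waters, from -5.54 to 3.21 after stormwater (SD 3.83) and from -5.36 to 2.19 after streamwater (SD 3.24). Both lowest values came from the distant arrays, where the probe was not well above background. The lowest values of the remaining arrays were -3.88 after stormwater and -2.84 after streamwater.

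**Figure D2:**
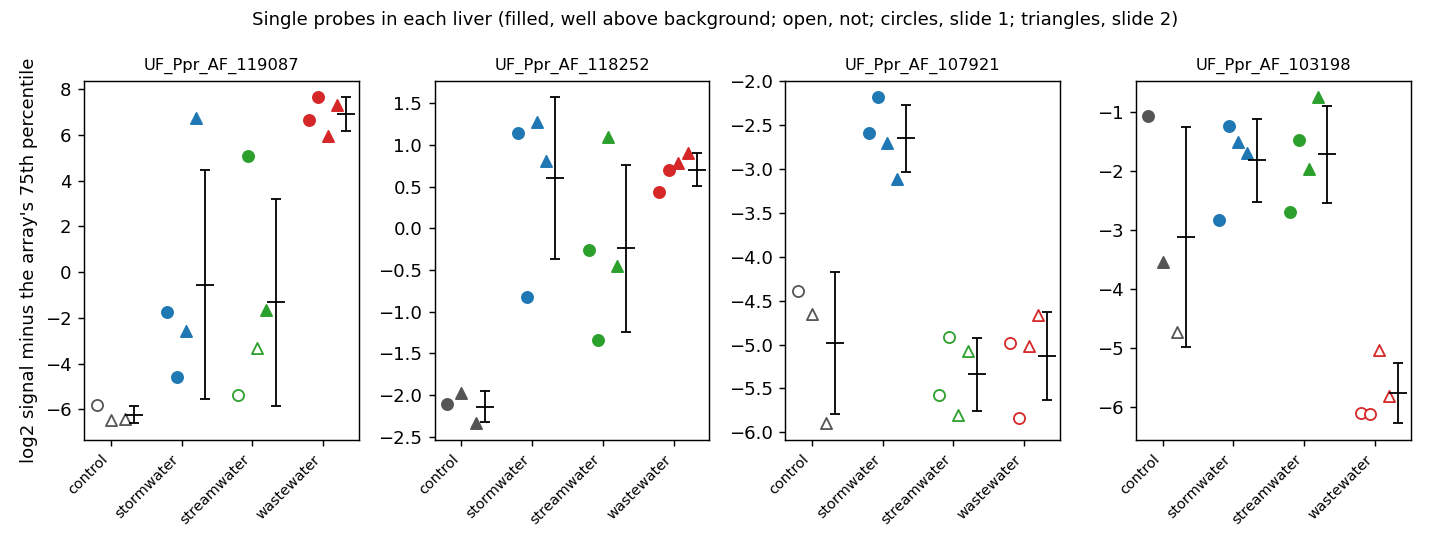
Levels of 4 probes in each liver, as log2 signal minus the array's 75th percentile, by water, with black bars for the mean and SD of each group. UF_Ppr_AF_119087 lies between 5.97 and 7.65 in the 4 wastewater livers and at -5.79 or below in the 3 controls, and UF_Ppr_AF_107921 is well above background (filled symbols) only in the 4 stormwater livers.

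The share of detected probes was compared with controls, and no difference passed after adjustment. After wastewater 61.3% ± 2.55 (SD, n = 4) of probes were well above background, against 71.5% ± 4.97 (SD, n = 3) in controls (two-sided exact permutation p = 0.0286, the smallest this design allows; 0.251 after Benjamini-Hochberg adjustment over 22 comparisons of array measures). After streamwater the share was 63.4% ± 2.52 (SD, n = 4, two-sided exact permutation p = 0.0571, adjusted 0.251). The shares after wastewater and streamwater were not shown to differ (exact permutation p = 0.314). On slide 1 the control had 65.8%, the wastewater arrays 64.7% and 60.6%, and the streamwater arrays 62.7% and 66.1%. On slide 2 the controls had 75.2% and 73.4%, the wastewater arrays 61.5% and 58.5%, and the streamwater arrays 60.2% and 64.5%. In a count chosen after the arrays were seen, 138 probes were well above background on all 3 control arrays and no wastewater array, and 1 probe, UF_Ppr_AF_119087, the other way. Of the 35 splits of these arrays, 1, the labelled one, gave as many as 138 (highest other 100), and 30 gave 1 or more. A share of 1 in 35 is the smallest this design allows, and the count uses the same detection calls as the shares above. For streamwater the counts were 101 and 1, and 2 of 35 splits gave as many as 101 (highest other 153). For stormwater they were 8 and 11, and 17 and 13 of 35 splits gave as many.

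At an unadjusted p under 0.05, 338 probes differed between wastewater and control, of which 90 were higher and 248 lower, fewer than the 582 given by chance. Quantile normalization gave 128 higher and 138 lower, the authors' values 129 and 116, and the normexp background 129 and 62, with the median log2 fold change at 0.00, 0.02 and 0.17 in place of -0.12. Among the 7170 probes well above background on all arrays 85 were higher and 77 lower. The levels of the groups did not overlap in 6.16% of probes, where chance gives 5.71% on average. The unadjusted count was 537 with slide as a block, with 0 probes passing, 197 within slide 1 (against 1 control array, with the spread of the other groups), 465 within slide 2 and 213 without control replicate 2.

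The effluents were then compared with each other, since a difference from control in one water and not in another needs its own test. Between stormwater and streamwater no probe passed limma's test. UF_Ppr_AF_107921 came closest, at -2.65 ± 0.38 (SD, n = 4) after stormwater and -5.34 ± 0.42 (SD, n = 4) after streamwater, where no array was well above background, and was at least 2.61-fold higher after stormwater (limma adjusted p = 0.0674). It passed with quantile normalization (adjusted p = 0.0374) and without control replicate 3 (adjusted p = 0.0206), with adjusted p from 0.0206 to 1.00 over all settings. At an unadjusted p under 0.05, 237 probes differed (74 higher and 163 lower after stormwater), and quantile normalization gave 110 and 120. The count was 149 without stormwater replicate 1, 443 without stormwater replicate 3, 684 without streamwater replicate 4, 743 within slide 1, 187 within slide 2 and 349 with slide as a block. The normexp background gave 26 higher and 1574 lower, with the median of all probes at -0.32 in place of -0.07, and no filter on dim probes gave 90 higher and 1395 lower.

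Between stormwater and wastewater the same probe, UF_Ppr_AF_107921, was at least 2.52-fold higher after stormwater (limma adjusted p = 0.164), and no probe passed. UF_Ppr_AF_103198 was well above background on all 4 stormwater and all 4 streamwater arrays and on no wastewater array, which puts it at least 4.46-fold and at least 4.79-fold higher (limma adjusted p = 0.231 and 0.216), and on 2 of 3 control arrays. At an unadjusted p under 0.05, 773 probes differed between stormwater and wastewater (530 higher and 243 lower after stormwater), with 711 within slide 1, 242 within slide 2 and 923 with slide as a block. In a count also chosen after the arrays were seen, on 68 probes all 4 stormwater arrays and no wastewater array were well above background, and 0 probes showed the opposite. Of the 70 splits of these arrays, 1, the labelled one, gave as many as 68 (highest other 58), the smallest share this design allows. The same count gave 17 probes for stormwater alone and 0 for streamwater alone, and 8 of 70 splits gave as many as 17. Between streamwater and wastewater it gave 6 and 2, which 23 and 55 of 70 splits reached. Stormwater arrays detected 69.8% ± 5.58 (SD, n = 4) of all probes, against 61.3% ± 2.55 (n = 4) after wastewater (two-sided exact permutation p = 0.0571, adjusted 0.251). Leaving out streamwater replicate 3, which changes only the error estimate, let 20 probes pass, all higher after stormwater. Leaving out control replicate 1 let UF_Ppr_AF_103198 pass (limma adjusted p = 0.0226), and leaving out control replicate 3 let UF_Ppr_AF_107921 pass (0.0497). Both also passed when only the 2 groups were fitted, as did other probes. Over all settings their adjusted p ran from 0.0195 and 0.0377 to 0.9995. Without stormwater replicate 2 the unadjusted count was 421, and the normexp background turned the split to 268 higher and 1574 lower, with a median of -0.38 in place of -0.09. Without a filter on dim probes (15208 tested) the split was 568 higher and 1579 lower.

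Between streamwater and wastewater no probe passed limma's test with all arrays, and 681 had an unadjusted p under 0.05, of which 435 were higher and 246 lower after streamwater. UF_Ppr_AF_103198 shared the lowest adjusted p, 0.216, with 2 other probes. It passed without control replicate 1 (limma adjusted p = 0.0171) and without streamwater replicate 3 (0.0429). The absence of passing probes rested on single arrays. Without streamwater replicate 3, 65 probes passed, most of them higher after streamwater, and the unadjusted count was 1263. Most probes that passed in that setting for stormwater against wastewater were among them, but both comparisons share the wastewater arrays. Streamwater replicate 3 correlated at 0.963 with wastewater replicate 4, the highest value of any pair of arrays. Without control replicate 1, 1 probe passed, and without streamwater replicate 4 the unadjusted count was 381. The unadjusted count was 403 within slide 1, 366 within slide 2 and 741 with slide as a block, and 266 with the normexp background. Leaving out both distant arrays gave 234 higher and 259 lower.

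A test for any difference among the 4 waters found 0 probes with limma at an adjusted p of 0.05 and 543 at an unadjusted p under 0.05. Without control replicate 1 or without streamwater replicate 3, 1 probe passed, and without streamwater replicate 3 the unadjusted count was 883. Leaving out both distant arrays, a choice made after the arrays were seen, left 0 passing probes in all 6 comparisons and among the 4 waters, with unadjusted counts of 866, 496 and 528 for stormwater, streamwater and wastewater against control.

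Across the 11640 probes, which are not independent replicates, the log2 fold changes of stormwater and streamwater against control correlated at r = 0.738. Unchanged groups, simulated together with 3 controls of their own, gave 0.573 on average, since the comparisons share the controls. The covariance was 0.338 against a simulated 0.293. The simulation drew each probe independently and gave the controls the spread pooled over all groups, distant arrays included. It therefore does not show what the 3 real controls give. When the labels of the 15 arrays were redrawn, which keeps the differences between arrays, the median was 0.577 and 21 of 100 draws were as high as 0.738. Without the 2 distant arrays the correlation was 0.506. Stormwater and wastewater correlated at 0.299 (simulated 0.572, covariance 0.127 against 0.294), and streamwater and wastewater at 0.328 (simulated 0.572, covariance 0.124 against 0.294). Redrawn labels gave medians of 0.568 and 0.576, with ranges of 0.08 to 0.904 and 0.042 to 0.879, so both values lay within what regrouped arrays give. Without the 2 distant arrays they were 0.493 and 0.536. The 3 controls are too few to be split into a pair of control groups, so part of any excess may come from the shared controls.

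Arrays also differed by slide. In limma's fit with both terms, 1229 probes differed between the 2 slides at an adjusted p of 0.05, of which 1182 were lower on slide 2, with a median absolute log2 difference of 0.95. Without the distant arrays slide accounted for 16.5% of the squared distance between arrays (exact permutation p = 5.83e-04), and with them for 10.06% (exact permutation p = 0.191). Each slide held arrays of all 4 waters.

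**Figure D3:**
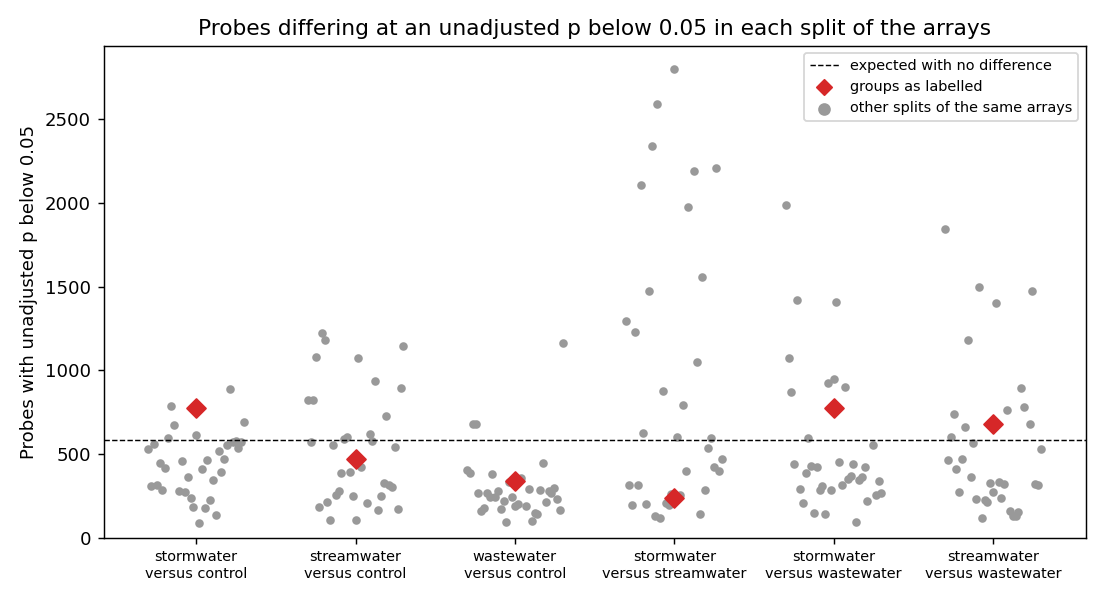
Number of probes with an unadjusted p under 0.05 (vertical axis) for the groups as labelled (diamonds) and for every other split of the same arrays into groups of the same sizes (grey points), in 6 comparisons. The labelled groups gave 774 probes for stormwater against control, where the highest other split gave 886, and 237 for stormwater against streamwater, where it gave 2803.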

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

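The tests of the slide behind the 2 distant arrays, the largest spike-in deviations, the count of lost bright probes, all tests of the probe bright in wastewater and the splits within slides were chosen after the results were seen, as was leaving out both distant arrays.

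Array measures and named probes were searched for samples far from the rest of their group of 4 (17 measures or probes in each of 3 groups), where chance gives about 5% of groups such a sample. This found 6 values. Stormwater replicate 2 stood apart in its first principal component score (143.2) and in its number of probes over 4-fold above their median (606), and streamwater replicate 4 in its mean correlation with the other arrays (0.789) and in its number of such probes (644). UF_Ppr_AF_105335 was low in streamwater replicate 3 (0.64) and UF_Ppr_AF_100386 high in streamwater replicate 2 (1.43), relative to the other streamwater livers.

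Stormwater replicate 2 and streamwater replicate 4 shared their difference from the other livers. They lay on different slides and correlated at 0.946 with each other, against at most 0.843 with any other array, which argues against the slide. Slide accounted for 1.03% of the variance of the first principal component. That share adds nothing, since these 2 arrays set the component and lie on different slides. The SD of their spike-in deviations (0.28, and 0.48 for streamwater replicate 4, on the log2 scale) lay below the highest of the other arrays (0.49), if narrowly for the latter, and no spike-in deviated by over 1.04 on either array, against a loss of over 4 for 28 of the 100 brightest probes on both, which argues against labelling, hybridization or scanning as the whole cause. RNA of another tissue in both samples stays open: 71 probes were detected on these 2 arrays alone, and the 98 of another pair, which the bound set beforehand counted against it, belong to stormwater replicate 2 itself with control replicate 2, while no pair without a distant array had over 28. RNA mostly of another tissue in place of liver RNA stays open too. The count of 28 lost bright probes (highest other pair 1) restates the pattern. On both arrays 21 probes lay over 4-fold above every other array, against 384 below. Relative to their median, 308 probes lay over 4-fold above on both and 714 below, so signal was gained as well as lost. None of these counts decides on this explanation. A state of these individual fish stays open as well.

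UF_Ppr_AF_119087 was bright in all 4 wastewater livers and not well above background in the 3 controls. Among the 35 splits of these 7 arrays 1, the labelled one, held a probe with as large a bound (11.39 on the log2 scale, highest other 6.97), but the measure was chosen for this probe in the most favourable of 6 comparisons, and as many probes detected in 1 group alone (1) came out in 30 of the 35 splits. Over all 6 comparisons 1 of 100 regroupings of the 15 arrays, the labelled one, gave as large a bound (highest other 10.84). This search covered all probes and both directions. The measure itself was still chosen after this probe's values were seen, so chance stays open. The wastewater means of the 2 slides differed by 0.51, against a difference of at least 11.39 between the wastewater and control means, which argues against the slide. The gap to the nearest control was 11.76 in the signals as read, but that control was not well above background. Exposure to wastewater is a candidate explanation, and differences between fish that have nothing to do with the water, or cross-hybridization of a single spot, were not tested.

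The 2 slides differed more than chance splits did: of 100 drawn splits of the 15 arrays, the real one included, 1 gave as many as 1229 probes, and the highest other gave 458. Quantile normalization left 79.0% of these probes passing, which argues against the 75th-percentile scaling as the cause. Of the 3 equal classes of probes by signal, the dimmest held 51.4% of them, the middle 42.6% and the brightest 5.94%, so few bright probes differed. The share of the dimmest class lay between the bounds set beforehand. It did not settle whether the local background of the slide acts on dim probes. No biological explanation was tested because the labels do not tie slides to aquaria or days.

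With splits that ignore the slide, chance could not be excluded for the counts of probes at an unadjusted p under 0.05. Of the 35 splits of the arrays of each pair of groups, as many or more probes came out in 3 for stormwater against control (774, highest other 886), 18 for streamwater against control (469, highest other 1221), 9 for wastewater against control (338, highest other 1165), 28 for stormwater against streamwater (237, highest other 2803), 9 for stormwater against wastewater (773, highest other 1986) and 10 for streamwater against wastewater (681, highest other 1843). Over the 4 waters, 43 of 100 drawn regroupings gave as many as 543, the highest 3795 with 775 passing an adjusted p of 0.05, which points to a structure of the arrays other than the waters. The split by slide gave 1148 for streamwater against control, 1165 for wastewater against control, 1298 for stormwater against streamwater, 1986 for stormwater against wastewater and 1843 for streamwater against wastewater, each above the labelled groups, and 693 for stormwater against control. Splits within each slide, with slide as a block, were too few for a share under 0.05 (18 per comparison). The labelled groups then gave 1443 for stormwater against control (highest other 817), 726 for streamwater against control (highest other 1467), 537 for wastewater against control (highest other 518), 349 for stormwater against streamwater (highest other 3018), 923 for stormwater against wastewater (highest other 1093) and 741 for streamwater against wastewater (highest other 1770). Over the 4 waters 25 of 100 such regroupings gave as many as 767.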

How the results depend on the processing

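Leaving out both distant arrays and the fits within slides were chosen after the data were seen. The main count of passing probes was 0 in every comparison, and it stayed at 0 in all but the following settings, whose cause was not tested except where named. With slide as a block 1 probe passed for stormwater against control (UF_Ppr_AF_112716), within slide 2 1 passed for streamwater against control (UF_Ppr_AF_100352), and quantile normalization let 1 pass for stormwater against streamwater (UF_Ppr_AF_107921). With only the 2 groups compared, which drops the spread of the other waters, 4 passed for wastewater against control and 18 for stormwater against wastewater. Leaving out 1 array gave 0 to 1 for streamwater against control (1 without control replicate 1) and for stormwater against streamwater (1 without control replicate 3). For stormwater against wastewater it gave 0 to 20 (20 without streamwater replicate 3, 1 without control replicate 1 or control replicate 3). For streamwater against wastewater it gave 0 to 65 (65 without streamwater replicate 3, 1 without control replicate 1). Among the 4 waters it gave 0 to 1 (1 without control replicate 1 or without streamwater replicate 3). The count stayed at 0 for stormwater against control and for wastewater against control.

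With the replicate block the passing counts were 0 in all comparisons, and the unadjusted counts were 744, 419 and 420 against control. Livers with the same number correlated at -0.46 to 0.39 in their deviations from the group means (mean 0.078, against -0.022 for different numbers), and 5 of 15 arrays correlated best with their own number. The replicates numbered 1 correlated at 0.131 to 0.290 with each other but share slide 1, so number and slide cannot be told apart there, and the numbers were not used as pairs.

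Unadjusted counts moved by over 1.5 times in 46 cases and stayed closer in 154. Array weights gave 779 probes for streamwater against control (469 in the main setting), 741 for wastewater against control (338), 771 for stormwater against streamwater (237), 1056 for streamwater against wastewater (681) and 1136 among the 4 waters (543). No filter (15208 tested) gave 1164, 632, 1485, 2147 and 1710 for stormwater and wastewater against control, stormwater against streamwater and against wastewater, and the 4 waters. The strictest filter (7170 probes tested, against 11640) gave 162 for wastewater against control and 499 for stormwater against wastewater (773 in the main setting). The normexp background gave 191 for wastewater against control, 1600 for stormwater against streamwater, 1842 for stormwater against wastewater and 266 for streamwater against wastewater, and only the 2 groups 627 for wastewater against control. Without both distant arrays the counts were 528 for wastewater against control and 541 for stormwater against streamwater, and with slide as a block as well 1541, 875 and 885 against control, 1047 for stormwater against streamwater and 1025 among the 4 waters. The 17 log2 fold changes of named probes that were refitted kept their sign in each setting that tested the probe, in 11 cases passing the threshold that the main value missed. The correlations moved without the distant arrays, to 0.506, 0.493 and 0.536. Tests of gene lists were not run, since no probe has a gene name. Signal over background limits the dim probes, for which ratios are bounds.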

Other observations

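The ranges of single probes and the comparison of the naming series were chosen after the values were seen, and the test of spot noise before.

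Single livers differed widely in a small set of probes. With signals not well above background raised to the lowest signal that was, on the same array, 147 probes had a range over 8 on the log2 scale over the 15 arrays, 35 without the 2 distant arrays and 7 within the 3 controls, and the median range of a probe was 1.99. UF_Ppr_AF_101592 had a range of at least 12.25, from control replicate 3, where it was not well above background, to 7.64 in streamwater replicate 3, with 7.44, 6.94 and 7.05 in wastewater replicates 2, 3 and 4 and -1.50 in wastewater replicate 1. UF_Ppr_AF_108485 had a range of at least 11.23, up to 6.16 in wastewater replicate 2.

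The array carries probes of 2 naming series, AF (14498 probes, 77.7% tested) and AM (710 probes, 53.7% tested), whose meaning the files do not state. For the 297 contigs with a tested probe of each series the mean levels of the pair correlated at -0.24 across contigs, and the AF probe was the brighter in 207. The median difference over all 297, AF minus AM, was 1.79 on the log2 scale, and different probes also differ in affinity.

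Noise of single spots was tested as the source of the spread between fish of a group through these pairs. Their deviations from the group means correlated at 0.228 over contigs and arrays, against 0.041 for pairs drawn at random. This lies under the bound set beforehand for spot noise, but the negative correlation of the levels, seen later, makes the pairs unfit for the test, and spot noise stays open. For stormwater replicate 2 and streamwater replicate 4 the deviations of all probes correlated at 0.768 with each other, which separate spots with noise of their own would not give.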
